A study of Arabidopsis thaliana with 4 samples.

How the data were processed

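RNA was taken from above-ground tissue of Arabidopsis thaliana plants aged 2.5 weeks, grown in 16 hours of light and 8 hours of dark. Per the labels' protocols, total RNA was given a poly(A) tail with poly(A) polymerase, reverse transcribed from an oligo(dT) primer, and amplified by nested PCR between a universal primer and primers for chosen Pol V transcripts. This is 3′ RACE, an assay that reads where an RNA ends. The PCR products of each genotype were pooled and sequenced as 1 library per genotype. All read names carried the same instrument, run and lane.

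The authors deposited 1 table per library, with 1 line per sequenced read. Each line gave the targeted locus, the read name, a mapping quality score, the strand, the genomic position of the 3′ end and a transcript length. Per the file headers, the last column is a transcript length in nt. Testing it against the coordinates showed that it is the distance of the 3′ end from a fixed position at each locus, with length 1 as the first counted base. The strands named below follow the direction in which this length grows. The deposited strand was the opposite one at every locus. Some ends lay at 1 nt, with 16.6% of the Col-0 ends at IGN17. At IGN35 they made up 7.88% in Col-0, 2.48% in rrp6L1-1 and 2.55% in rrp6L1-2. PCR from a locus primer needs the primer site upstream of the end. These values therefore argue against length 1 being the 5′ end of the RNA at these loci. Whether the fixed position is set by the primer was not tested, and the primer positions were not used here. The deposited mapping quality score ran from 41 to 44 in every library. The submitters' processing notes name bcl2fastq 2.16.0.10, cutadapt 1.9.1, Bowtie2, SAMtools and bedtools with the TAIR10 genome; their roles and settings are not given in the sources used here. Coordinates were read as 1-based TAIR10 positions and looked up in the NCBI copy TAIR10.1. The genomic base at the 3′ end was A for at most 1.42% of the ends at any locus outside IGN5t in Col-0 and both rrp6L1 libraries. A trimmed poly(A) tail leaves such a pattern, because A bases of the genome next to the tail are removed with it. An end can therefore lie further downstream than recorded, by the length of the genomic A run.

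In the Col-0 table, every IGN17 read stood on a pair of identical lines, 27611 lines being repeats. Each read was counted once. Counting lines as deposited was tried as an alternative. After this step the libraries held 141489 reads for Col-0, 248940 for nrpe1-11, 109895 for rrp6L1-1 and 89304 for rrp6L1-2.

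A locus was a run of end positions on 1 strand, using positions with at least 5 ends over the 4 libraries and joining those within 200 nt. This gave 8 runs. The 7 used here matched the 7 locus names of the authors 1 to 1, and the remaining run, downstream of IGN23, held ends of nrpe1-11 and was not used for medians. Between 6 and 21 reads per library lay outside the 7 spans. A locus needed at least 100 ends in each library compared. Displacement was the median length in a mutant minus the median in Col-0, positive in the direction of transcription. Its 95% interval came from 2000 bootstrap resamples of the ends, and intervals of medians within a library came from order statistics. Shares were given exact Clopper-Pearson intervals. A locus was called displaced when both rrp6L1 libraries moved the same way by at least 10 nt with intervals excluding 0. All 7 loci passed the depth minimum and all are named, by a rule fixed, like the thresholds and most alternatives, before the data were examined. The distances between whole profiles (Kolmogorov-Smirnov distance) and the shares at single positions were added once the tables had been read. The prediction for the distances was written before they were computed.

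There was 1 library per genotype, so no difference has a replicate check and no p-value was computed. The reads carry no molecular identifiers and passed through nested PCR, so reads are not independent molecules. Intervals and detection limits cover counting error only and are narrower than the true uncertainty. For a share of 0%, the upper end of the exact interval is given, which is higher than the floor of 3 reads first planned. Shares of a locus in a library reflect pooled PCR products and not RNA abundance.

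The alternatives changed the joining gap, the depth minimum, the measure of location, the weight of each position, the use of positions before genomic A, the depth and the size threshold. Where distinct positions were counted once for displacements and tails, positions with a single end in a library were left out, and intervals were wide because few positions remained. The displacement step was tested on simulated ends drawn from the Col-0 profiles at rrp6L1-1 depth. The test covered 1 mutant library against Col-0, and not the demand that both alleles move. At the 7 loci, 0 of 140 draws with no shift passed 10 nt with an interval excluding 0, 128 of 140 with a shift of 10 nt and 140 of 140 with a shift of 20 nt. The draws held counting error only, with no uneven PCR copying and no spread between libraries. The 0 is therefore not a rate of false calls for these libraries. A list of 14 genes fixed beforehand (the mutated genes, other genes of RNA-directed DNA methylation, household genes, FLC and IPS1), with nuclear rRNA, snoRNA, snRNA and tRNA genes and the organelle genomes, held 0 reads in the 4 libraries, since the tables list targeted loci. The reads therefore do not check the genotypes through the mutated genes. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used Matplotlib 3.10.9.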

Results

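The 3′ ends of transcripts made by RNA polymerase V (Pol V), a plant polymerase whose noncoding transcripts guide DNA methylation, were read at 7 loci in 4 genotypes. Col-0 was the wild type. The nrpe1-11 mutant carries a mutation in the gene for the largest Pol V subunit and served as the control without Pol V. The rrp6L1-1 and rrp6L1-2 mutants are 2 independent alleles of RRP6L1, a relative of the exosome-associated 3′-to-5′ exonuclease RRP6. The question was whether the transcripts ended at other positions when this exonuclease was mutated. Each genotype was represented by 1 library, so none of the values below has a replicate error. The only guide to the spread between libraries is the difference between the rrp6L1 alleles. Depth was 141489 reads in Col-0, 248940 in nrpe1-11, 109895 in rrp6L1-1 and 89304 in rrp6L1-2.

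None of the 7 loci overlapped an annotated gene in TAIR10.1. IGN5b and IGN5t lie beside each other on chromosome 4 and run apart, IGN5b on the plus strand from 2323304 to 2323466 and IGN5t on the minus strand from 2323136 down to 2323000. The nearest gene downstream of IGN5b is APR1 (AT4G04610), which encodes an enzyme of sulfate assimilation and starts 1412 nt away. The next gene beyond IGN5t is the lncRNA gene AT4G04905, 690 nt away. IGN23 (chromosome 4, 2577995 to 2578176, plus strand) starts 21 nt from the 5′ end of the oppositely transcribed gene AT4G05030. The other neighbour of IGN23, AT4G05040, starts 418 nt beyond its downstream edge. IGN25 (chromosome 4, 5459179 to 5459373, plus strand) lies between AT4G08570, 3079 nt away, and AT4G08580, 2025 nt away. IGN35 (chromosome 4, 6549083 to 6549314, plus strand) lies 205 nt from the 5′ end of AT4G10600. IGN29 (chromosome 2, 15314845 to 15315109, plus strand) starts 38 nt from the 5′ end of DML1 (AT2G36490, also called ROS1), the gene of a DNA demethylase transcribed the opposite way. IGN17 (chromosome 1, 13585662 to 13585864, plus strand) lies between pseudogenes at distances of 4666 and 8650 nt.

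Counted from length 1 in the direction of transcription, the first 110 nt of the reference were as follows. The IGN5b sequence is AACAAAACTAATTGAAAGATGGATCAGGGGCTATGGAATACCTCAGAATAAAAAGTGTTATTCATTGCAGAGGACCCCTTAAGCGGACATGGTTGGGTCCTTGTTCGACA. For IGN5t, on the minus strand, it is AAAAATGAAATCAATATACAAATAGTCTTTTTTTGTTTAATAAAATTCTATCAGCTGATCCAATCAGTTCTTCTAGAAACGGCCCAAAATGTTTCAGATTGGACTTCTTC. IGN17 reads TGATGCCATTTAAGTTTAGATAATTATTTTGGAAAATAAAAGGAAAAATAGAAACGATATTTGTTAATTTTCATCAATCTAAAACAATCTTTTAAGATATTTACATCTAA. IGN23 begins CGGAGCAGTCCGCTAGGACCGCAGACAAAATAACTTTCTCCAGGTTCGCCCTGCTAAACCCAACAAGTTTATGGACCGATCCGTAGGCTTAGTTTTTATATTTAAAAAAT. IGN25 begins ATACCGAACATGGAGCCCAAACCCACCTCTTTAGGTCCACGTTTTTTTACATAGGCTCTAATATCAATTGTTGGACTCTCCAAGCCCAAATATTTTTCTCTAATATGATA. IGN29 is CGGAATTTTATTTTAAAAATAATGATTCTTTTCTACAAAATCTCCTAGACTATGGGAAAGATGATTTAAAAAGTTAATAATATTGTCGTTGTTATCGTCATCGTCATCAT. IGN35 is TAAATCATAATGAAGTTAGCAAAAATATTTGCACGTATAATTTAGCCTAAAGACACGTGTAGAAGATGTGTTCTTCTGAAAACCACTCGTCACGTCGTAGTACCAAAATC.

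The nrpe1-11 library held reads at IGN23 and almost nowhere else. In nrpe1-11, 248926 of 248940 reads came from IGN23, 99.99% of the library (exact 95% interval 99.991% to 99.997%). The other 6 loci together gave 14 reads: 4 at IGN5b, 3 at IGN29, 3 at IGN35, 2 at IGN17, 2 at IGN25 and 0 at IGN5t, the last allowing a share of up to 0.00148% by its exact interval. In Col-0 each locus held between 6.04% (IGN5t) and 20.1% (IGN25) of the reads. The rrp6L1-1 shares ran from 8.47% (IGN17) to 22.1% (IGN23), and the rrp6L1-2 shares from 7.84% (IGN5t) to 20.4% (IGN17). These are shares of pooled PCR products, and the pooled amount was not tied to the amount of RNA.

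The IGN23 ends of nrpe1-11 also differed in form from those of Col-0. At length 40 nt (position 2578034) lay 92.1% of them, while the same position held 0.192% of the Col-0 ends, 0.243% of the rrp6L1-1 ends and 0.170% of the rrp6L1-2 ends. Ends of 36 to 46 nt made up 99.5% of the nrpe1-11 total. The median end was 40 nt in nrpe1-11 and 55 nt in Col-0, a difference of -15 nt (95% counting interval -15 to -15 nt). Col-0 ends were spread over IGN23, with 16.8% at 97 nt, 8.95% at 6 nt and 8.38% at 55 nt. The nrpe1-11 and Col-0 profiles had 1.91% of their ends in common, position by position. IGN23 was the 1 locus deep enough for this comparison, so the form of the ends without Pol V could not be compared at the other 6.

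**Figure D1:**
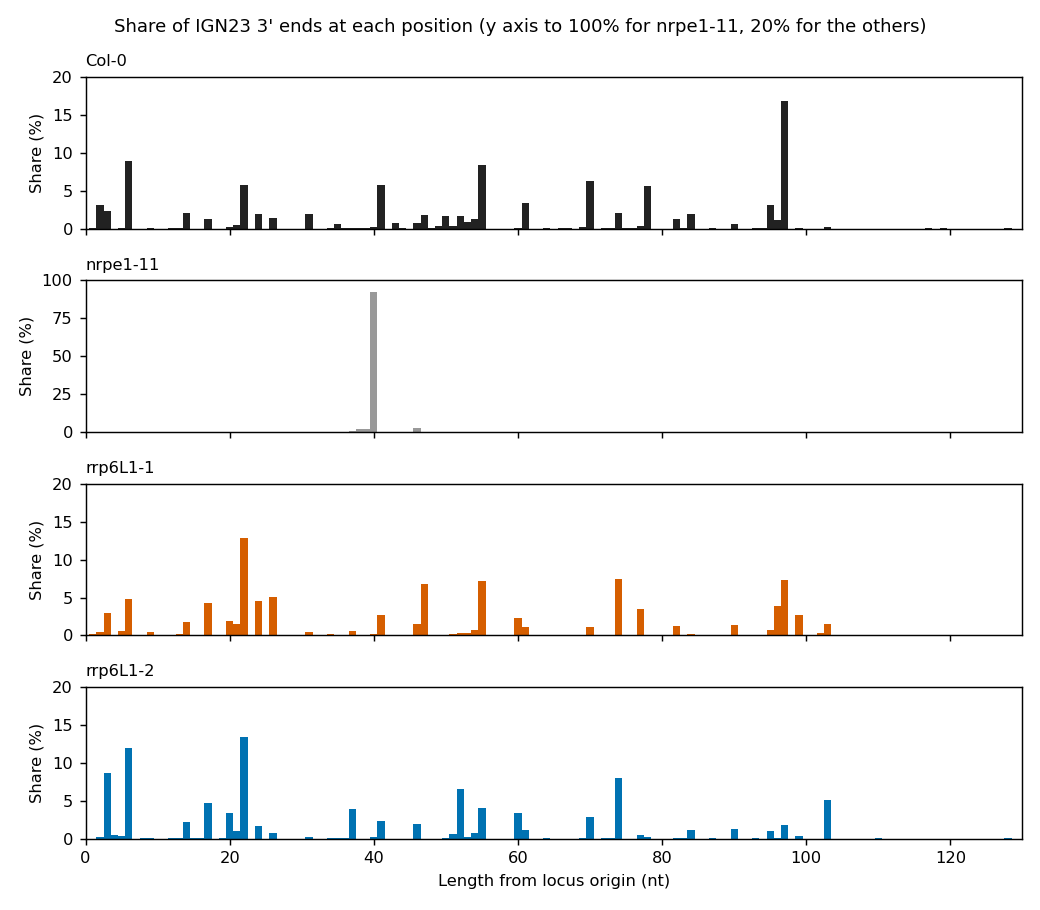
Share of IGN23 3′ ends (y axis, percent of the ends of each library) at each length from the locus origin (x axis, nt) in the 4 libraries, 1 library per genotype; the y axis reaches 100% for nrpe1-11 and 20% for the others. A single position, 40 nt, held 92.1% of the nrpe1-11 ends, while the ends of the other 3 libraries were spread over many positions.

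Mutation of RRP6L1 did not move the 3′ ends of the 7 loci in a single direction. By the rule set for the comparison, which used medians, 2 of 7 loci were displaced the same way in both alleles: IGN25 downstream and IGN35 upstream. Both alleles were set against the same Col-0 library, so their agreement in direction is not an independent replication. Downstream displacements that missed the rule were seen at IGN5b and IGN5t, and an upstream one at IGN23, which was large in rrp6L1-2 and small in rrp6L1-1. IGN29 ended within 1 nt of Col-0 by its median in both mutants, and at IGN17 the median and the mean moved opposite ways. Over the 7 loci, the median displacement was 1 nt in rrp6L1-1 (95% counting interval 1 to 1 nt) and 6 nt in rrp6L1-2 (6 to 8 nt). The sign depended on the measure: -0.18 and -1.78 nt by the mean, and -1 and -10 nt with each distinct position counted once. By the mean, these were the values of IGN29, where the rrp6L1-1 interval of -0.794 to 0.458 nt included 0. The number of displaced loci depended on the measure too, with 4 by the mean and 0 with distinct positions. Other alternatives, many of which kept the 2 calls, are given below.

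**Figure D2:**
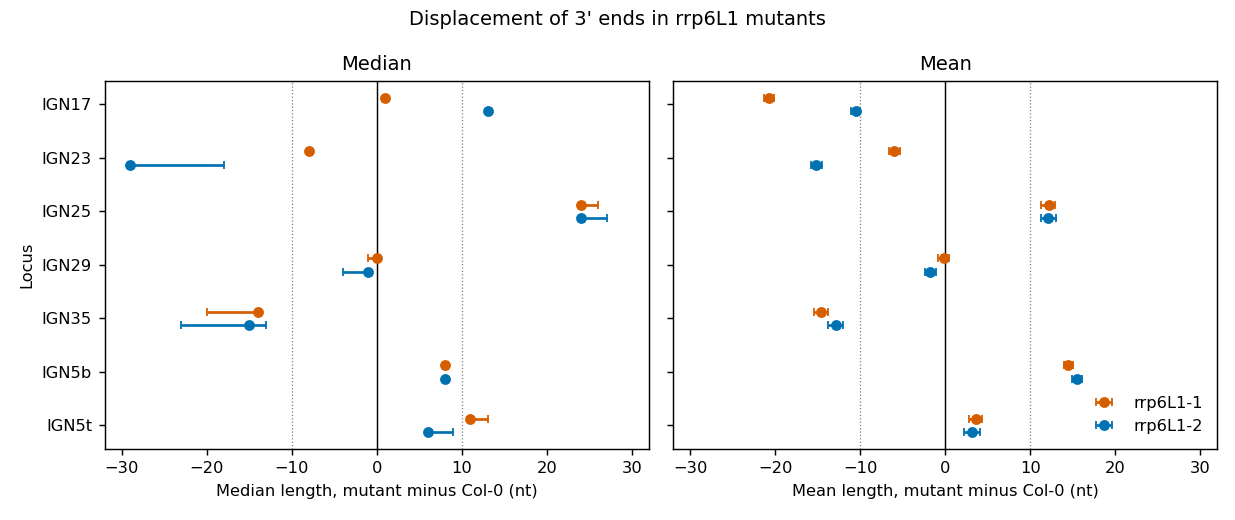
Median (left) and mean (right) 3′ end length in rrp6L1-1 and rrp6L1-2 minus that in Col-0 (x axis, nt, positive in the direction of transcription) at the 7 loci (y axis); points are single libraries, bars are 95% bootstrap intervals for counting error, and dotted lines mark 10 nt. IGN25 and IGN35 passed 10 nt in both alleles by the median, in opposite directions, and at IGN17 the mean lay below Col-0 in both alleles while the median did not.

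At IGN25 the transcripts of both mutants ended further downstream than those of Col-0 by the median, but not at every length. The median was 50 nt in Col-0 (28395 ends), 74 nt in rrp6L1-1 (10629 ends) and 74 nt in rrp6L1-2 (13843 ends). Both displacements were 24 nt, with counting intervals of 24 to 26 nt and 24 to 27 nt. Ends at 48, 50 and 52 nt, which held 6.59%, 11.2% and 8.66% of the Col-0 ends, held under 0.1% each in both mutants. Long ends at 140 nt fell too, from 10.5% in Col-0 to 0.0564% in rrp6L1-1 and 3.07% in rrp6L1-2. The length that 90% of the ends did not exceed was 140 nt in Col-0, 98 nt in rrp6L1-1 and 142 nt in rrp6L1-2. The positions gained differed between the alleles. In rrp6L1-1, 31.9% of the ends lay at 98 nt (position 5459276), where rrp6L1-2 had 0.00722%. In rrp6L1-2, 13.0% lay at 86 nt and 8.17% at 145 nt, where rrp6L1-1 had 0.226% and 0% (upper end of the exact interval 0.0347%). Leaving out the most frequent position of each library turned the rrp6L1-1 displacement to -5 nt, and counting each distinct position once turned it to -14 nt, while rrp6L1-2 stayed downstream at 36 and 11 nt.

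IGN35 showed the opposite displacement. Its median fell from 43 nt in Col-0 (14375 ends) to 29 nt in rrp6L1-1 (20026 ends) and 28 nt in rrp6L1-2 (13641 ends). The displacements were -14 nt (counting interval -20 to -14 nt) and -15 nt (-23 to -13 nt), and the alleles differed by 1 nt. Ends at 20 nt (position 6549102) were more frequent in both mutants, at 12.4% and 14.3% against 6.16% in Col-0. Ends at 104 nt were less frequent, at 0.649% and 0% (upper end of the exact interval 0.0270%) against 7.02%. So were ends at 1 nt, at 2.48% and 2.55% against 7.88%. The alleles parted at 26 nt (4.78% in rrp6L1-1 and 0.359% in rrp6L1-2 against 0.501% in Col-0). They also parted at 62 nt (0.629% and 6.37% against 5.51%) and at 91 nt (0.0549% and 4.57% against 4.62%). At 69 nt, 6.22% of the rrp6L1-1 ends and 5.59% of the rrp6L1-2 ends stood against 0.292% in Col-0. Counting each distinct position once gave displacements of -8 and -17 nt and ended the call. Leaving out the first 10 nt gave -29 nt in both alleles, and leaving out positions before a genomic A gave -28 and -44 nt.

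IGN5b moved downstream in both alleles by 8 nt, below the 10 nt required, from a median of 36 nt to 44 nt in each. The mean rose from 38.2 nt to 52.6 nt in rrp6L1-1 and 53.7 nt in rrp6L1-2. With the most frequent position of each library left out, the displacements parted to 53 and 18 nt, without positions before A-rich genomic sequence to 44 and 21 nt, and without positions before any genomic A, an alternative chosen after seeing the data, to -49 and 0 nt. IGN5b passed the 10 nt rule downstream under the first 2 of these and by the mean. The position at 44 nt (2323347) held 25.9% of the rrp6L1-1 ends and 21.1% of the rrp6L1-2 ends, and 0.0634% of those in Col-0. Conversely, 25 nt held 18.0% of the Col-0 ends against 0.00560% and 0.671%. At 36 nt the alleles parted, with 34.3% in Col-0, 16.7% in rrp6L1-2 and 0.756% in rrp6L1-1. Farther downstream, 80 and 86 nt were frequent in rrp6L1-1 (21.9% and 13.3%) against 0.0317% and 0.756% in Col-0. The position at 92 nt held 24.9% in rrp6L1-2, 6.73% in Col-0 and 0% in rrp6L1-1 (upper end of the exact interval 0.0207%). At 73 nt lay 12.1% of the Col-0 ends, against 0.0448% in rrp6L1-1 and 0% in rrp6L1-2 (upper end 0.0317%).

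On the opposite strand, IGN5t had medians of 17 nt in Col-0 (8538 ends), 28 nt in rrp6L1-1 (12886 ends) and 23 nt in rrp6L1-2 (6996 ends). These were displacements of 11 nt (counting interval 11 to 13 nt) and 6 nt (6 to 9 nt), and the alleles differed by 5 nt. The most frequent position was 12 nt (2323125) in all 3 libraries, with 25.5% of the Col-0 ends, 15.4% of the rrp6L1-1 ends and 18.7% of the rrp6L1-2 ends. Mean lengths differed less, at 30.3, 33.9 and 33.4 nt. Counting each distinct position once gave displacements of 0 and -22 nt, and leaving out positions before A-rich genomic sequence gave 2 and 4 nt.

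IGN23 ended nearer its origin in both mutants, by unequal amounts. From 55 nt in Col-0, the median fell to 47 nt in rrp6L1-1 and 26 nt in rrp6L1-2, displacements of -8 nt (counting interval -8 to -8 nt) and -29 nt (-29 to -18 nt). The difference of 21 nt between the alleles exceeded the displacement in rrp6L1-1. Without the most frequent position of each library the displacements were 4 and -9 nt, without the first 10 nt -13 and -9 nt, and without positions before a genomic A -4 and 0 nt. The position at 97 nt, 16.8% of the Col-0 ends, held 7.30% in rrp6L1-1 and 1.82% in rrp6L1-2, while 22 nt held 12.9% and 13.5% against 5.74% in Col-0.

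The IGN17 profiles had little in common. Col-0 ends fell into a short group, with 16.6% at 1 nt, 21.1% at 17 nt and 15.3% at 30 nt, and a long group at 102, 104 and 106 nt with 21.4%, 10.2% and 2.72%. That long group was almost missing from the mutants, where each of its positions held at most 0.0107%. Instead, 66.8% of the rrp6L1-1 ends lay at 31 nt (position 13585692) and 51.9% of the rrp6L1-2 ends at 43 nt (13585704). The medians were 30, 31 and 43 nt, and the means 49.7, 29.0 and 39.2 nt, so the mutants were 20.8 and 10.5 nt shorter than Col-0 by the mean and 1 and 13 nt longer by the median. The call at IGN17 depended on the measure: upstream by the mean, downstream without the most frequent position of each library (13 and 15 nt), and none with each distinct position counted once (-36 and -19 nt, not both with an interval excluding 0).

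IGN29, beside DML1, changed least. Its medians were 33 nt in Col-0, 33 nt in rrp6L1-1 and 32 nt in rrp6L1-2, with displacements of 0 nt (counting interval -1 to 0 nt) and -1 nt (-4 to -1 nt). The same end positions recurred: 14 nt (15314858) held 17.2%, 16.9% and 16.6% of the ends in the 3 libraries, and 46 nt held 5.92%, 6.62% and 8.87%. Shares differed at 34 nt (14.9%, 10.2% and 7.17%) and at 3 nt (7.60%, 13.0% and 15.1%). Position by position, Col-0 had 82.1% of its ends in common with rrp6L1-1 and 79.0% with rrp6L1-2, and the alleles had 83.6% in common.

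**Figure D3:**
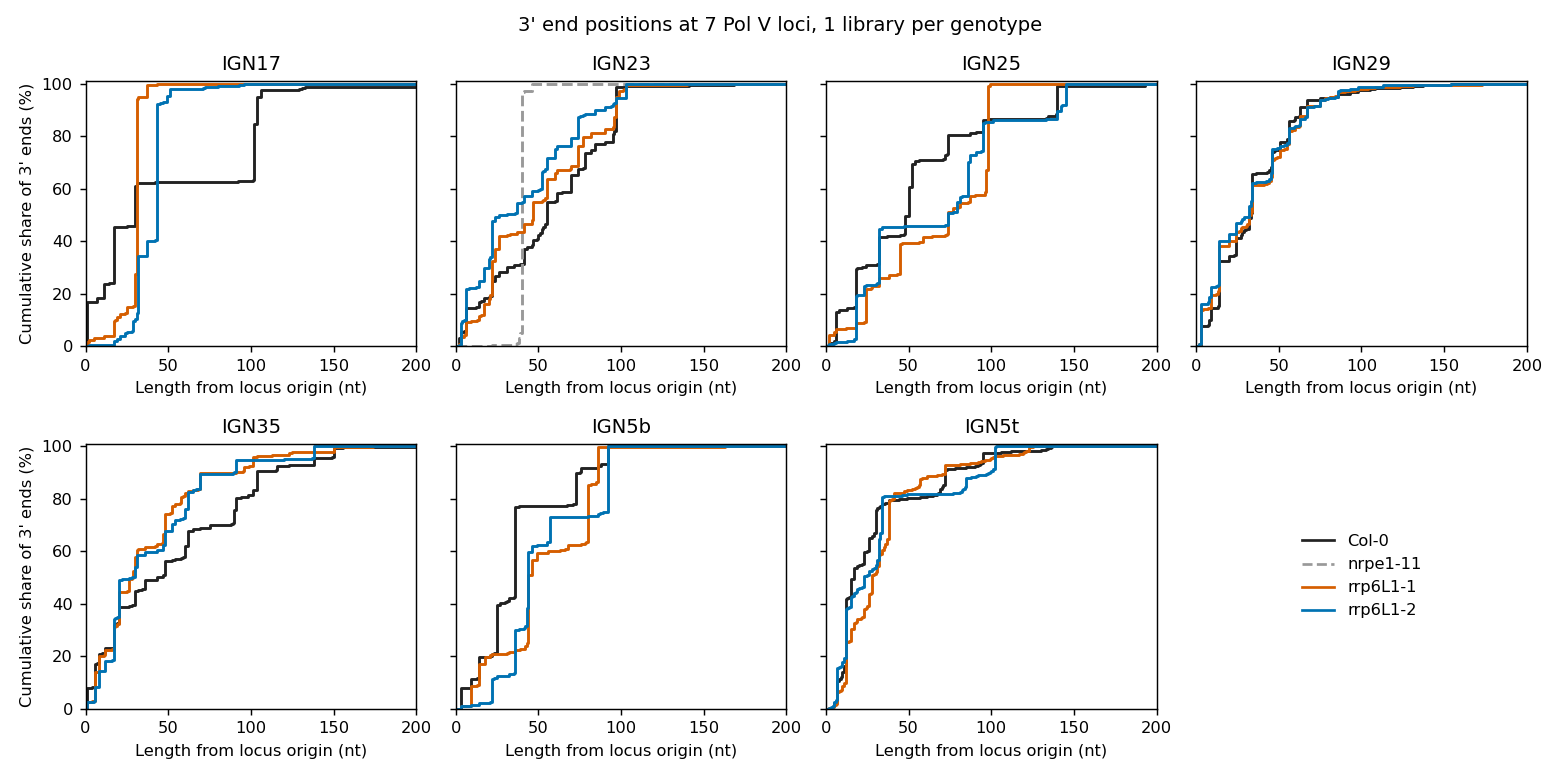
Cumulative share of 3′ ends (y axis, percent) against length from the locus origin (x axis, nt) at the 7 loci, with 1 line per library; nrpe1-11 is drawn where it had at least 100 ends, at IGN23. The 3 lines of IGN29 nearly coincide, while those of IGN17, IGN25 and IGN5b rise in large steps at positions that differ between libraries.

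The tail of long products gave a mixed result as well. Taking the shortest length that at least 90% of the Col-0 ends did not exceed as the limit, ends beyond it were more frequent than in Col-0 in both mutants at 3 of 7 loci and less frequent in both at 2. They were more frequent at IGN5b (37.4% in rrp6L1-1 and 27.0% in rrp6L1-2 against 9.98%), at IGN29 (12.5% and 13.4% against 9.05%) and at IGN23 (5.27% and 5.65% against 1.26%). The IGN5b limit fell on a Col-0 peak at 73 nt, and with ends at the limit included its shares were 37.5% and 27.0% against 22.0%. The IGN23 limit fell on the Col-0 peak at 97 nt, and with ends at the limit included the direction turned, to 12.6% and 7.47% against 18.1%. They were less frequent at IGN17 (0.0107% and 0.0879% against 5.12%) and IGN35 (3.51% and 5.23% against 9.52%). At IGN25 the alleles parted, with 0.0941% and 10.4% against 1.04%, and also at IGN5t, with 7.25% and 18.1% against 8.83%. The IGN25 limit of 140 nt was itself a Col-0 peak. With ends at the limit included, the alleles still parted, but IGN25 gave 0.151% and 13.4% against 11.5%, and IGN5t 10.4% and 18.1% against 14.6%. The median difference from Col-0 over the loci was -0.945 percentage points in rrp6L1-1 (95% counting interval -1.08 to -0.781) and 4.39 in rrp6L1-2 (4.15 to 5.20). The sign of these medians depended on the percentile and on whether each distinct position was counted once, and their size on whether ends at the limit were included.

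Distances between whole profiles set the difference from Col-0 against the difference between the alleles. By the Kolmogorov-Smirnov distance, the largest gap between cumulative shares, the alleles were the closest pair of the 3 libraries at 5 of 7 loci, where chance would give 2.33. The margin was widest at IGN5b, with 0.253 between the alleles and 0.547 and 0.469 from Col-0, and at IGN35, with 0.0836 against 0.232 and 0.207. At IGN25 (0.272 against 0.313 and 0.299), IGN5t (0.202 against 0.237 and 0.210) and IGN29 (0.0423 against 0.0628 and 0.0869) the margins were small. The alleles lay farther apart than either from Col-0 at IGN17 (0.817 against 0.375 and 0.510), and at IGN23 their distance of 0.152 fell between 0.144 and 0.236. By the share of ends in common, position by position, the alleles were the most alike pair at 4 of 7 loci. They were the least alike pair at IGN25, with 17.7% in common against 42.2% for Col-0 and rrp6L1-2 and 19.5% for Col-0 and rrp6L1-1, and at IGN5t, with 52.1% against 53.5% and 55.5%.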

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

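The 16 alternatives left the 2 displaced loci, IGN25 downstream and IGN35 upstream, as the only calls under 10 settings. These were a smaller and a larger joining gap, minimums of 20 and 1000 ends per library, a minimum of 1 end per position, thinning, the demand that a displacement exceed the difference between the alleles, and, chosen after seeing the data, lines counted as deposited, the first 10 nt left out and positions before a genomic A left out. Without the first 10 nt, IGN35 moved to -29 nt in both alleles. Without positions before a genomic A it moved to -28 and -44 nt, IGN5b to -49 and 0 nt, and the median over loci to 0 nt in rrp6L1-2. Apart from thinning and the last 2, these settings left both loci unchanged and say nothing about their stability. With the mean, 4 loci were displaced (2 downstream, IGN25 and IGN5b, and 2 upstream, IGN17 and IGN35), and the median over loci was -0.18 nt in rrp6L1-1 and -1.78 nt in rrp6L1-2. With each distinct position counted once, 0 loci were displaced (0 downstream, 0 upstream) and the medians were -1 and -10 nt. Leaving out the most frequent position gave 2 downstream loci, IGN17 and IGN5b but not IGN25, and a rrp6L1-1 median of 4 nt. Leaving out positions before A-rich genomic sequence gave 2 downstream loci, IGN25 and IGN5b, and medians of 0 and 4 nt. A smallest displacement of 5 nt gave 5 loci (3 downstream, 2 upstream), and one of 25 nt gave 0 (0 downstream, 0 upstream), by construction. IGN25 in rrp6L1-1 reversed to -14 nt with distinct positions and to -5 nt without the most frequent position, while IGN35 kept its sign but lost its call with distinct positions (-8 nt in rrp6L1-1). The tail difference over loci became 2.99 and 1.40 percentage points (rrp6L1-1, rrp6L1-2) beyond the 75th percentile, 20.8 and 9.28 beyond the 50th, -3.16 and -4.61 with distinct positions, and, chosen after seeing the data, -5.52 and 1.903 with ends at the limit included. Without its most frequent position, an alternative added later, the IGN23 median in nrpe1-11 lay -11 nt from Col-0. Its share of the library did not change when counted at loci only, and 1 locus was deep enough at a minimum of 20 ends too. Distinct positions put IGN23 at 13.7% of Col-0, 80.3% of nrpe1-11, 16.3% of rrp6L1-1 and 15.4% of rrp6L1-2. Of 224 displacements of single loci under the alternatives, 161 stayed within the counting interval and 11 changed sign, at IGN17, IGN23, IGN29, IGN5b and IGN5t besides IGN25. Most of the 161 came from settings that left every displacement as it was. These were the joining gaps, the depth minimums, 1 end per position, the size thresholds, the allele rule and lines as deposited. The 161 is therefore no measure of stability. Beyond the constructions named, the cause of the changes was not tested. No paired analysis was possible because each genotype has 1 library. The number of molecules behind the reads is unknown.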

Other observations

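The tests of the nrpe1-11 product and of single end positions below were chosen after the result was seen; those of genomic A runs and of profile distances were written before. In nrpe1-11, 21 IGN23 reads ended far downstream of the rest, between 488 and 979 nt (positions 2578482 to 2578973), a range that runs into the 5′ part of AT4G05040. Over all loci, the longest product was 242 nt in Col-0, 265 nt in rrp6L1-1 and 192 nt in rrp6L1-2.

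Some end positions were common to Col-0 and both rrp6L1 alleles, and others were found in Col-0 alone. Over the 7 loci, 11 positions held 5% or more of the ends in all 3 libraries, among them 12 nt at IGN5t and 14 nt at IGN29. Another 11 reached 5% in Col-0 and stayed under 1% in both mutants, 7 did so in rrp6L1-1 alone and 6 in rrp6L1-2 alone. The balance depended on the limit, with 22 common and 14 in Col-0 alone at 3%, and 2 and 5 at 10%. The Col-0 group included 102 and 104 nt at IGN17 and 48, 50 and 52 nt at IGN25.

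The differences between rrp6L1 and Col-0 may be spread between single libraries in part. At single positions, 2 were high in both mutants and low in Col-0 (44 nt at IGN5b and 69 nt at IGN35), while 2 were high in Col-0 and rrp6L1-1 only and 3 in Col-0 and rrp6L1-2 only; limits of 3% and 10% gave 4, 4 and 6 and 1, 1 and 1. Counting positions high in 1 library too, which was added later, 13 set Col-0 apart, 10 rrp6L1-1 and 8 rrp6L1-2 (18, 15 and 15 at 3%; 6, 6 and 4 at 10%), so the narrow and the wide count point different ways. The alleles were the closest pair by whole profile at 5 of 7 loci and by ends in common at 4, which does not decide, because loci of the same 3 libraries are not independent and the design has no second library of any genotype. An effect of the exonuclease stays open, also at IGN35, where the alternatives that moved the displacement kept its sign in both alleles but counting distinct positions once ended the call, and so do differences between plants and between PCR reactions.

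The single IGN23 product of nrpe1-11 is unlikely to be reads of other libraries with the wrong index, since only 0.206% of the 62083 pooled IGN23 ends of the other 3 libraries lay at its position against 92.1% in nrpe1-11. Priming of oligo(dT) on a genomic A stretch is argued against by the sequence, with 1 A among the 10 genomic nt after the end. PCR copies of 1 or a few molecules stay a candidate explanation: the effective number of end positions was 1.18, against 15.4, 18.6 and 15.4 in Col-0, rrp6L1-1 and rrp6L1-2, but this value restates the pattern and cannot separate copies from a transcript of another polymerase with a sharp end. The test had been written so that a value below 2 would count for PCR copies; that reading was withdrawn after the value was seen, because a sharp pattern makes it low whatever the source.

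Of the ends, 77.1% in Col-0, 66.1% in rrp6L1-1 and 72.7% in rrp6L1-2 lay before a genomic A, while 35.3% of the counted bases were A. Removal of genomic A with the poly(A) tail would raise this share by itself, so 35.3% is not the share to expect. How far such trimming raised the share was not computed. Priming of oligo(dT) on genomic A stretches could add to it: per genomic base that can give such an end, ends before 3 or more A were 1.71 times as frequent as ends before no A in Col-0, 0.868 times in rrp6L1-1 and 2.29 times in rrp6L1-2. Against it, the ratios before 1 or 2 A were 3.34, 1.53 and 1.86, above those for longer runs in Col-0 and rrp6L1-1. Ends before windows with at least 6 A in 10 nt made up 19.95% in Col-0 but 38.3% and 40.2% in the mutants. Much of this lay at IGN17 (31 nt in rrp6L1-1, 43 nt in rrp6L1-2) and IGN5b (44 nt in both), each followed by 8 A in 10 nt. This difference cannot decide, because every library was primed with oligo(dT) and no share of such windows among the counted bases was set beside it. These values leave priming open, and the 66.8% of IGN17 ends at 1 position in rrp6L1-1, which a G follows, weigh on that library's ratio.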
